A study of Mus musculus with 6 samples.

How the data were processed

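Total RNA from mouse E14 embryonic stem cells of strain 129/Ola was measured on 6 Illumina bead arrays, 3 for each of the 2 Lsd1 (Kdm1a) genotypes. Per the labels, the RNA was extracted with Trizol, cleaned on a column with DNase treatment, and turned into biotinylated cRNA with an Illumina TotalPrep kit. The samples were grouped by the genotype in their labels. The series text calls the 3 samples of each genotype biological replicates and does not say whether they were separate clones, so p-values measure the spread between these samples.

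The authors deposited a table of non-normalized intensity values, 1 linear signal per probe and array, for 45281 probes. Its lowest signal per array lay between 36.0 and 39.7 and its median between 73.8 and 83.7, so no background had been subtracted. Beside each signal the deposited table gives a detection p-value, and each p-value column fell with the signal of its own array with 0 rank violations and with at least 15232 when set against another array. The authors' value table of the series holds intensity values on the same linear scale: on each array they were the non-normalized signals times 1 constant, from 11.9 to 13.6, which set every array's median to 1000. The scanner software, its settings and the way the detection p-values were made are not given in the sources used here. No column of another sample was left unused.

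Probes were named from the platform annotation that came with the value table, which can be old. Of the 45281 probes, 34885 had 1 gene symbol, 18 had several and 10378 had none, and the last groups were given no gene. Symbols were updated through a RefSeq gene table of assembly GRCm38.p6, which matched 34818 of the single-symbol probes. Neither deposited table names a genome build, so this assembly served for names and for the chromosome of a gene, and coordinates are not given. The probe sequences were not used here, so the place of a probe within its transcript, and whether it also binds a near-identical gene copy, was not examined.

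The non-normalized signals were background corrected with limma's nec function, which estimated the background from the detection p-values, with an offset of 16, and then quantile normalized and taken to log2. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept, which left 19652 probes, of which 16711, or 85.0%, had 1 gene symbol. Each gene was represented by 1 probe, the one with the highest mean over the 6 arrays, which gave 10711 genes. Genotypes were compared with limma (lmFit and eBayes) on all 6 arrays with the genotype as the single term, two-sided, and p-values were adjusted with Benjamini-Hochberg over the 10711 genes, with a threshold of 0.05. Differences are given as Δ3/Δ3 minus Lox/Δ3 on the log2 scale with their standard error, and means with their SD over 3 arrays. Where a gene was detected on none of the arrays of a genotype, its fold is a lower bound, taken against the higher, on each array, of the gene's own value and the lowest value among detected probes. The offset of 16 pulls fold changes of weak genes toward 1. R 4.3.3 and limma 3.58.1 were used, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

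The 22 gene lists were pluripotency, LSD1 complex partners, primitive streak and mesoderm, Hox clusters, endoderm, trophectoderm, neural progenitor, REST-silenced neuronal, two-cell stage, germline, imprinted, retinoic acid pathway, p53 targets and apoptosis, cell cycle, DNA methylation, other H3K4 enzymes, post-implantation epiblast, adhesion and EMT, blood and endothelium, fibroblast (feeder) markers, stress response and Y-linked genes. Of these, 21 had at least 3 tested genes and were tested as sets with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 21 lists, and beside it with camera at an estimated correlation and with fry. Fry asks whether the genes of a list changed at all, not whether they changed more than other genes. Its test for change in either direction is given only where it passed. Members past the threshold were counted over all genes and adjusted over the list alone. The median of each of 20 chromosomes with at least 20 tested genes was set against 10000 random gene sets of its size, two-sided, with Benjamini-Hochberg adjustment over the chromosomes.

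Genes were named by a rule: Kdm1a; the 12 largest rises and 12 largest falls among genes past the threshold whose arrays did not overlap between genotypes; from each list up to 4 members past the threshold, smallest p first, or otherwise 2 with the smallest p, given as values; and always Pou5f1, Nanog, Sox2, Rcor1, Rcor2, Hdac1, Hdac2, T, Hoxb7, Hoxd8 and Rarg. No probe with T or Hdac1 as its single symbol was tested, so these 2 are not analysed here. The comparison, its tests, the lists, the naming rule and the alternatives were chosen before the data were examined, apart from those named as chosen later. The alternatives were other background corrections, normalizations, the authors' scaled values, other filters on weak probes, other ways to combine probes, other variance models and weights, a block for the replicate number, stricter thresholds, and each array left out in turn.

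The procedure was tested on simulated data for the Δ3/Δ3 against Lox/Δ3 comparison, with 10740 simulated genes passing the filter. It recovered 22.7% of the genes changed 1.5-fold, 83.3% of those changed 2-fold and 96.9% of those changed 4-fold, and 7 of its 140 calls were unchanged genes. None (0) of 20 simulated unchanged lists passed, and 1 of 1 shifted list did. The simulated genes varied independently, so this does not test camera where genes of a list move together. Between 40.9% and 43.7% of probes were detected per array, and the median detected signal was 4.24 to 5.46 times the median of the undetected probes. The number of arrays, 3 per genotype, limits the precision.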

Results

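Gene expression was profiled in mouse embryonic stem cells carrying a deletion of exon 3 of Lsd1 (current symbol Kdm1a), the gene of a histone demethylase that removes methyl groups from lysine 4 of histone H3. E14 is a mouse embryonic stem cell line of strain 129/Ola. Cells with exon 3 deleted on both alleles (Δ3/Δ3) were compared with cells that had 1 deleted allele and 1 allele with exon 3 flanked by loxP sites (Lox/Δ3), with 3 arrays per genotype. The question was which transcripts change when the intact allele is lost. The arrays detected 18506 to 19799 probes each, the fewest on Lox/Δ3 array 1, and their median raw signals lay between 73.8 and 83.7. Pearson correlations of the log2 values across genes, which are not independent replicates, were 0.977 to 0.990 between arrays of 1 genotype and 0.966 to 0.985 between genotypes. The component that held most variance, 46.4%, had all Δ3/Δ3 arrays on one side and all Lox/Δ3 arrays on the other, with Lox/Δ3 array 1 farthest out.

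Kdm1a transcript fell 2.94-fold in Δ3/Δ3 cells. Its single named probe (ILMN_1254253) measured 10.39 ± 0.18 in Δ3/Δ3 and 11.94 ± 0.17 in Lox/Δ3 cells (log2, mean ± SD, n = 3 each), a log2 fold change of -1.56 ± 0.15 (SE) with a limma Benjamini-Hochberg adjusted p of 0.0128. The values on the Δ3/Δ3 arrays, 10.56, 10.20 and 10.41, all lay below those on the Lox/Δ3 arrays, 12.06, 11.76 and 12.01. Transcript was detected on all 6 arrays, and whether the probe lies within exon 3 was not examined. Without any 1 of the Δ3/Δ3 arrays the difference stayed between -1.46 and -1.64 but its adjusted p rose to between 0.0744 and 0.0939.

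In Δ3/Δ3 cells 110 genes rose and 30 fell. Of the 12 largest rises 10 lay between 3.37-fold and 4.51-fold, and for Otog and Omt2a, not detected in the control cells, lower bounds are given. Among the 10 were the X-linked germ-cell antigen genes Magea5 and Magea2, the class II histocompatibility gene H2-Eb1 and the cation channel gene Pkd2l1. The 12 largest falls, between 2.03-fold and 3.11-fold, included the calcium pump gene Atp2a3, Kdm1a itself, the synaptic genes Cplx1 and Lrfn3 and the hedgehog pathway transcription factor Gli2. The pluripotency factors Pou5f1, Nanog and Sox2 were not among the called genes. All 140 genes had an adjusted p under 0.05 in limma with Benjamini-Hochberg adjustment over 10711 genes, changed by at least 1.5-fold and showed no overlap between the arrays of the genotypes.

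Minar2 rose 4.51-fold, from 5.36 ± 0.66 to 7.53 ± 0.033 (log2, mean ± SD, n = 3; log2 fold change 2.17 ± 0.29 SE; limma adjusted p = 0.0281). H2-Eb1 rose 4.42-fold, from 6.66 ± 0.85 to 8.81 ± 0.13 (limma adjusted p = 0.0390). Magea5, a member of the melanoma antigen family normally expressed in testis, rose 4.22-fold (limma adjusted p = 0.0281), and its relative Magea2 rose 3.54-fold (limma adjusted p = 0.0281). Otog, which encodes otogelin of the inner ear membranes, was detected on all Δ3/Δ3 arrays and on no Lox/Δ3 array and rose at least 3.25-fold (limma adjusted p = 0.00784). The oocyte gene Omt2a, likewise detected on no Lox/Δ3 array, rose at least 2.52-fold (limma adjusted p = 0.0128). The other large rises were 1700080O16Rik (3.96-fold), Pkd2l1 (3.88-fold), the chemokine gene Ccl25 (3.55-fold), the phospholipase gene Pla1a (3.42-fold), the zinc finger gene Zscan5b (3.38-fold) and the metallothionein gene Mt3 (3.37-fold), with limma adjusted p-values from 0.0281 to 0.0487. Without Lox/Δ3 array 2 the calls of Pkd2l1 and Pla1a were lost (limma adjusted p = 0.0530 and 0.0531). Minar2 and Magea5 were detected on 2 of the 3 Lox/Δ3 arrays. Other probes of Ccl25 differed, with log2 fold changes of 0.92 and -0.29. Genes such as Magea5, Magea2 and Omt2a have close relatives whose transcripts their probes may also bind.

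Among the falls, Atp2a3 dropped 3.11-fold, from 8.63 ± 0.16 to 6.99 ± 0.16 (log2, mean ± SD, n = 3; log2 fold change -1.63 ± 0.14 SE; limma adjusted p = 0.0112), and its other probe had a log2 fold change of -1.43. Cplx1, which encodes complexin 1 of synaptic vesicle fusion, fell 2.56-fold (limma adjusted p = 0.0281), and Lrfn3, which encodes a synaptic adhesion protein, fell 2.44-fold (limma adjusted p = 0.0194). Gli2 fell 2.06-fold from a high level, 10.66 ± 0.35 to 9.62 ± 0.083 (limma adjusted p = 0.0431). The remaining falls were Gm9918 (2.89-fold), the muscle cytochrome oxidase subunit gene Cox6a2 (2.65-fold), the endothelial nitric oxide synthase gene Nos3 (2.29-fold), the transcription factor gene Foxn4 (2.23-fold), Wdr90 (2.21-fold), the small GTPase gene Diras1 (2.05-fold) and the transglutaminase gene Tgm1 (2.03-fold), with limma adjusted p-values from 0.0223 to 0.0408. In Δ3/Δ3 cells Cox6a2 was detected on 2 arrays and Foxn4 on 1. A further probe differed in size for Lrfn3, at -0.26, and for Gli2, at -0.036. The calls of Cox6a2, Cplx1, Nos3, Gli2, Diras1 and Tgm1 were lost without Lox/Δ3 array 1 (limma adjusted p from 0.0559 to 0.109) and without Lox/Δ3 array 2 (0.0531 to 0.0995), and that of Wdr90 without Lox/Δ3 array 2 (0.0501).

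**Figure D1:**
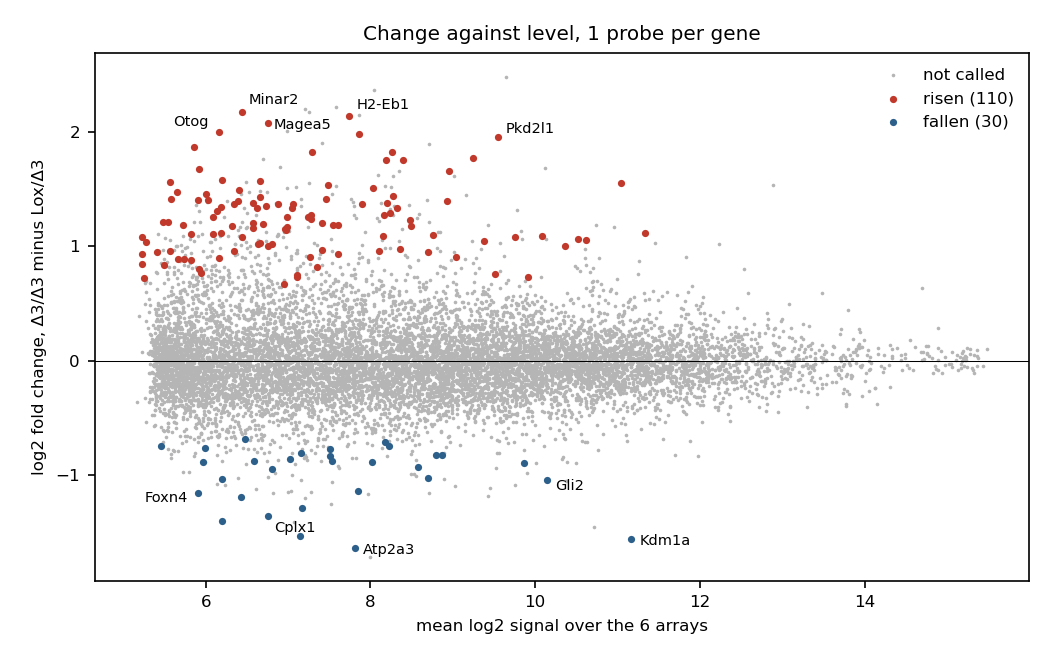
Log2 fold change (Δ3/Δ3 minus Lox/Δ3) against the mean log2 signal over the 6 arrays, 1 point per gene for 10711 genes. The 110 risen genes (red) and 30 fallen genes (blue) passed an adjusted p of 0.05, and most lie at the weaker end of the signal range; the median level was 6.96 for risen, 7.34 for fallen and 8.38 for all genes tested.

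**Figure D2:**
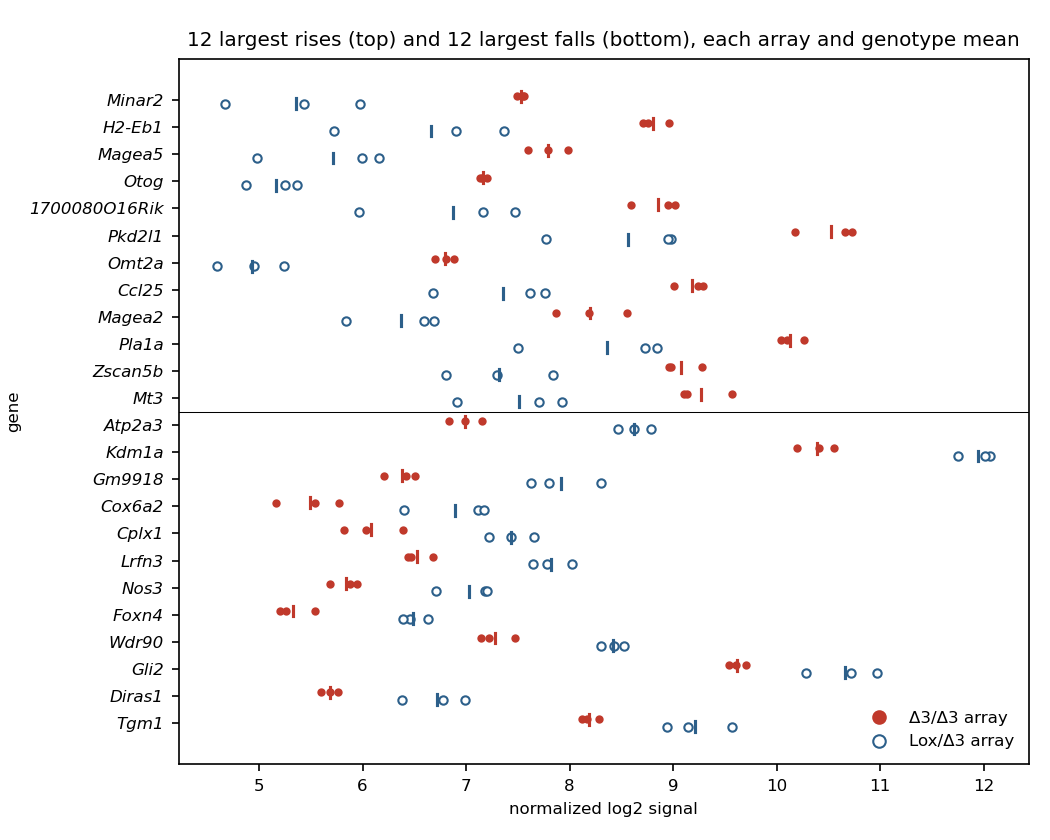
Normalized log2 signal of the 12 largest rises (top) and 12 largest falls (bottom) on each array, filled for Δ3/Δ3 and open for Lox/Δ3, with a vertical bar at each genotype's mean (n = 3). The genotypes do not overlap in any of the 24 genes, and the Lox/Δ3 arrays spread more widely in most of the risen genes.

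Of the 110 risen genes, 90 had a mean level over the 6 arrays at or below the median of all genes tested. Of these 110, 19 were detected on no Lox/Δ3 array and 68 on all 3 of them, and of the 30 fallen genes 26 were detected on all Δ3/Δ3 arrays. Of 35 called genes with another kept probe, 34 had every other probe on the same side, the exception being Ccl25. The risen genes varied more between the Lox/Δ3 arrays, with a median SD of 0.271 against 0.167 in Δ3/Δ3, and 97 of the 110 had their lowest control value on Lox/Δ3 array 1. Without that array the median log2 fold change of the 110 genes was 1.07, against 1.20 with it. Over all genes tested, 2548 (23.8%) did not overlap between the genotypes, where chance gives 10% for each gene. In limma 1946 had an unadjusted p under 0.05, 1039 higher and 907 lower in Δ3/Δ3. A split that mixed the genotypes, Δ3/Δ3 array 1 with Lox/Δ3 arrays 1 and 2 against the rest, gave 1579 such genes. The other mixed splits gave 51 to 562, so such a count is not by itself evidence of a genotype effect. The number of calls depended on every array: no gene (0) passed limma's adjusted threshold without Δ3/Δ3 array 1, 2 or 3, where 1551, 1798 and 1600 genes had an unadjusted p under 0.05, and 45, 63 and 275 passed without Lox/Δ3 array 1, 2 and 3. All 140 genes had an unadjusted p under 0.05 in each of these fits, but the fits reuse the arrays that selected the genes, so this is no separate support. With no filter on weak probes 22 of the 140 stayed called, and with cyclic loess in place of quantile normalization 111, without H2-Eb1, 1700080O16Rik, Pla1a and Gli2.

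The 27 tested pluripotency genes showed no call in either direction. Pou5f1 measured 13.15 ± 0.14 in Δ3/Δ3 and 13.36 ± 0.11 in Lox/Δ3 cells (log2, mean ± SD, n = 3; limma adjusted p = 0.450), Nanog 13.53 ± 0.19 and 13.47 ± 0.19 (limma adjusted p = 0.887), and Sox2 9.86 ± 0.096 and 9.79 ± 0.15 (limma adjusted p = 0.813). The signs of the small Nanog and Sox2 differences turned under some alternatives. The list's median log2 fold change was -0.087, its mean 0.034, and camera pointed down with an adjusted p of 0.662. Dppa3, a gene of naive stem cells and germ cells, had the largest difference of any list member, 10.89 ± 0.035 against 8.41 ± 1.39, a log2 fold change of 2.48 ± 0.58 (SE) that did not pass (limma adjusted p = 0.0777). Without Lox/Δ3 array 1 its log2 fold change was 1.71 and its limma adjusted p 0.0267. Tet1, which oxidizes 5-methylcytosine, had a log2 fold change of -0.59 (limma adjusted p = 0.0913). No pluripotency gene passed when adjusted over the list alone (0).

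None of the 19 tested LSD1 complex partners was called, over all genes or adjusted over the list alone (0). The corepressor genes Rcor1 and Rcor2 both had log2 fold changes of -0.20, and Hdac2 had 0.11 on its main probe and -0.16 on another (limma adjusted p from 0.452 to 0.748). Gatad2b was at -0.44 and Ctbp2 at -0.37 (limma adjusted p = 0.179 and 0.201). The list's median was -0.10, with 15 of 19 genes lower (camera adjusted p = 0.192). Of 18 other H3K4 enzymes, with Kmt2b at -0.40 and Wdr5 at -0.37, and of 8 DNA methylation genes, with Tet1 and with Uhrf1 at -0.19, none was called over all genes. Their medians were -0.062 and -0.18 (camera adjusted p = 0.433 and 0.153), with 0 and 1 genes passing when adjusted over the list alone.

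Of the genes on the lineage lists, 1 was called. Of 13 tested neuronal genes silenced by REST, a repressor that works with LSD1, Cplx1 fell, 10 were lower and 3 higher, and 5 passed when adjusted over the list alone. The list's median was -0.24 (camera adjusted p = 0.0884, and 0.656 with an estimated correlation). Without Lox/Δ3 array 3 it was -0.43 (camera adjusted p = 0.0244, and adjusted p = 0.486 with an estimated correlation). Fry's test for change in either direction gave an adjusted p of 0.00491, and its test for a shared direction 0.190. Of 10 tested Hox genes none passed over all genes and 4 when adjusted over the list alone. Hoxd8 had a log2 fold change of 1.12 ± 0.23 (SE), Hoxb7 of 0.84 ± 0.18 and Hoxc9, detected on no Lox/Δ3 array, was higher in all Δ3/Δ3 arrays (limma adjusted p = 0.0598, 0.0628 and 0.0548). The median of the Hox list was 0.18 (camera adjusted p = 0.153, and 0.656 with an estimated correlation). Fry's adjusted p was 0.0163 for either direction and 0.190 for a shared direction. In the retinoic acid list of 9 genes, Rarg, which encodes a retinoic acid receptor, was at -0.99 ± 0.26 (limma adjusted p = 0.106) and Crabp1 at 0.66 (limma adjusted p = 0.0557); its median was -0.15 (camera adjusted p = 0.796) and 2 genes passed adjusted over the list alone. Another probe of Rarg stood at -0.89, with a limma adjusted p of 0.0342 where each of the 19652 kept probes was tested on its own. The study's published account names Hoxb7, Hoxd8 and Rarg, so their values and the counts that include them are not independent evidence.

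In the primitive streak and mesoderm list (10 tested genes), Evx1 was at 0.96 and Eomes at 0.44, and the median was 0.022 (camera adjusted p = 0.571). Foxa1 at 0.76 and Sox7 at -1.09 were the endoderm genes with the smallest p, with a list median of -0.019 over 18 genes (camera adjusted p = 0.796). Lox/Δ3 array 3 stood apart in several endoderm genes: Col4a1 was at 12.72 on it and at 10.45 and 10.42 on the other Lox/Δ3 arrays, and Lama1 at 12.23 against 10.39 and 10.34. Without that array the endoderm list passed upward, with a median of 0.29 (camera adjusted p = 0.0221, and adjusted p = 0.602 with an estimated correlation). Trophectoderm genes had a median of 0.18 over 18 genes, with Tfap2a at 0.49 and Eomes at 0.44 (camera adjusted p = 0.192), and passed upward without Lox/Δ3 array 3, at 0.53 (camera adjusted p = 0.00207, and adjusted p = 0.486 with an estimated correlation). In the neural progenitor list of 9 genes, with Map2 at 0.72 and Otx2 at 0.61, the median was 0.079, the mean -0.010 and camera's direction up (camera adjusted p = 0.662). Post-implantation epiblast genes had a median of 0.29, with 9 of 10 higher, among them Lefty2 at 1.69, which was 2.32 without Lox/Δ3 array 2, and Otx2 (camera adjusted p = 0.0884). That list passed without Δ3/Δ3 array 3, at 0.45 (camera adjusted p = 0.0360, and adjusted p = 0.619 with an estimated correlation), and without Lox/Δ3 array 2, at 0.62 (0.00338 and 0.624). Adhesion and EMT genes had a median of 0.21 over 14 genes, with Cdh3 at 0.91 and Zeb1 at 0.67 (camera adjusted p = 0.0884), and passed without Lox/Δ3 array 2, at 0.38 (camera adjusted p = 0.0287, and adjusted p = 0.624 with an estimated correlation). Blood and endothelium genes had a median of 0.15 over 9 genes, with Tek at 0.81 and Lmo2 at 0.61 (camera adjusted p = 0.192). No gene (0) of these 7 lists was called over all genes. Adjusted over the list alone, 1 neural progenitor gene and 2 blood and endothelium genes passed, and 0 in each of the other 5 lists.

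Genes of the two-cell embryo stage were lower in Δ3/Δ3 cells as a set. Of 15 tested, 13 were lower, the median log2 fold change was -0.49 and the mean -0.35, and camera gave an adjusted p of 0.0171, the 1 list of 21 past the threshold. With an estimated correlation, which was 0.68 in this list, camera's adjusted p = 0.656 ended the call, and fry gave an adjusted p of 0.416. The call was also lost with median scaling, with the authors' values, with a stricter filter and with array weights, and without Δ3/Δ3 array 1 (camera adjusted p = 0.0806), Δ3/Δ3 array 2 (0.118) or Lox/Δ3 array 3 (0.101). No member was called over all genes, and 2 passed adjusted over the list alone. Arg2 was at -1.20 ± 0.24 (SE; limma adjusted p = 0.0565), and Pramel7 went the other way, at 2.01 ± 0.44 (limma adjusted p = 0.0659).

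Of 20 tested germline genes 11 were higher and 9 lower, none was called over all genes and 10 passed when adjusted over the list alone. The median was 0.19 (camera adjusted p = 0.292, and 0.749 with an estimated correlation). Fry's test for change in either direction had an adjusted p of 0.00182, and its test for a shared direction 0.458. The testis tubulin gene Tuba3a was at 0.91 ± 0.17 (SE; limma adjusted p = 0.0531) and Dpep3 at 0.92 ± 0.21 (limma adjusted p = 0.0776). Among 17 imprinted genes, Usp29, a paternally expressed neighbour of Peg3, rose at least 2.22-fold, being detected on no Lox/Δ3 array (limma adjusted p = 0.0281), and 14 of 17 were higher, with a median of 0.098 (camera adjusted p = 0.0884; 1 gene passed adjusted over the list alone). The imprinted list passed without Lox/Δ3 array 2, at 0.26 (camera adjusted p = 0.0312, and adjusted p = 0.624 with an estimated correlation), and without Lox/Δ3 array 3, at 0.21 (0.0221 and 0.486). The call of Usp29 was lost without Lox/Δ3 array 1 (limma adjusted p = 0.0607) and without Lox/Δ3 array 2 (limma adjusted p = 0.0531).

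Markers of stress, growth and other cells gave no call over all genes. The p53 and apoptosis list had a median of 0.10 over 17 genes, with Cdkn1a at 0.72 and Gadd45a at -0.50 (camera adjusted p = 0.292). The cell cycle list had a median of -0.080 over 22 genes, with Cdkn2a at 0.39 and Ccna2 at -0.40 (camera adjusted p = 0.313). The stress response list had a median of 0.0012 over 15 genes, with Junb at 0.54 and Trib3 at -0.89 (camera adjusted p = 0.796). Fibroblast markers, which would show feeder cells, had a median of 0.034 over 9 genes (camera adjusted p = 0.214), although Thy1 was at 1.61 ± 0.30 (SE) and Mmp2 at 0.97 ± 0.20 (limma adjusted p = 0.0522 and 0.0599). Adjusted over the list alone, 2 fibroblast markers passed and 0 genes of the other 3 lists. Uty, the 1 of 7 listed Y-linked genes that was tested, was at -0.097 (limma adjusted p = 0.813). Its means, 5.83 in Δ3/Δ3 and 5.93 in Lox/Δ3 cells, lay near the lowest detected values per array, 5.36 to 5.56. It therefore says little about the Y chromosome.

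**Figure D3:**
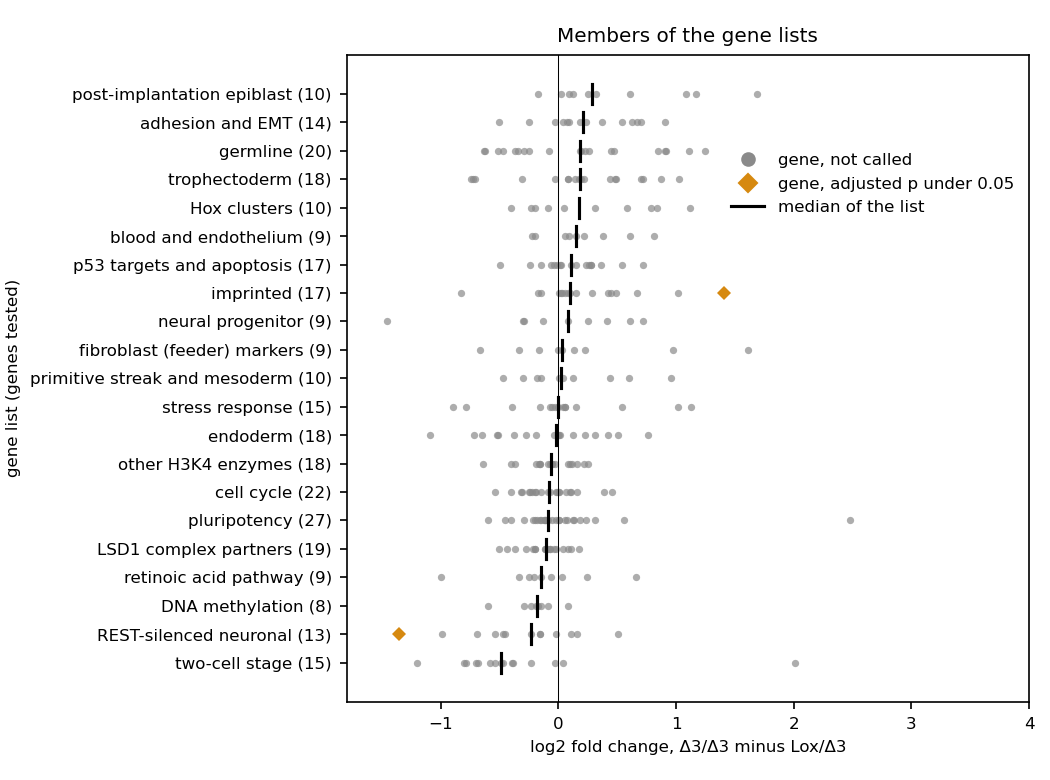
Log2 fold change of every tested member of 21 gene lists (Δ3/Δ3 minus Lox/Δ3), with the number of tested genes in brackets and a black bar at the median of each list. Orange diamonds mark the members with an adjusted p under 0.05 over all genes, Usp29 and Cplx1; the medians run from -0.49 for the two-cell stage to 0.29 for the post-implantation epiblast.

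Genes on the X chromosome were slightly higher in Δ3/Δ3 cells as a group. The median log2 fold change of 381 X-linked genes lay 0.125 above that of all genes, and 68.2% of them were higher in Δ3/Δ3 against 45.5% of autosomal genes. The X held 17 of the 110 risen genes and 0 of the fallen ones, where 3.92 risen genes would fall there by their number (two-sided Fisher exact p = 3.1e-07). Among these 17 were Magea5, Magea2 and 1700080O16Rik, and 5 were Mage genes. The Fisher test takes genes as independent, which members of a family need not be. With 1 gene per family of shared symbol stem, 13 of 306 X-linked families and 87 of 5077 others held a risen gene (one-sided Fisher exact p = 0.00404). The chromosome of each gene was that of assembly GRCm38.p6. Against 10000 random gene sets, 7 of 20 chromosomes had a shifted median at an adjusted p under 0.05. The X had an adjusted p of 0.001, from the smallest p these sets can give, 0.0001. Chromosomes 1, 13 and 18 lay above the median of all genes, by 0.0461, 0.0397 and 0.0482, and chromosomes 8, 11 and 15 below it, at -0.0398, -0.0340 and -0.0367. Relative to autosomal genes, the X-linked median on the Δ3/Δ3 arrays was 0.0898, 0.0933 and 0.0630 and on the Lox/Δ3 arrays -0.111, -0.0654 and -0.0485, as deviations from each gene's mean (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). Random sets treat genes as independent, which genes of 1 chromosome need not be, and camera with an estimated correlation gave the X a p of 0.0112.

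**Figure D4:**
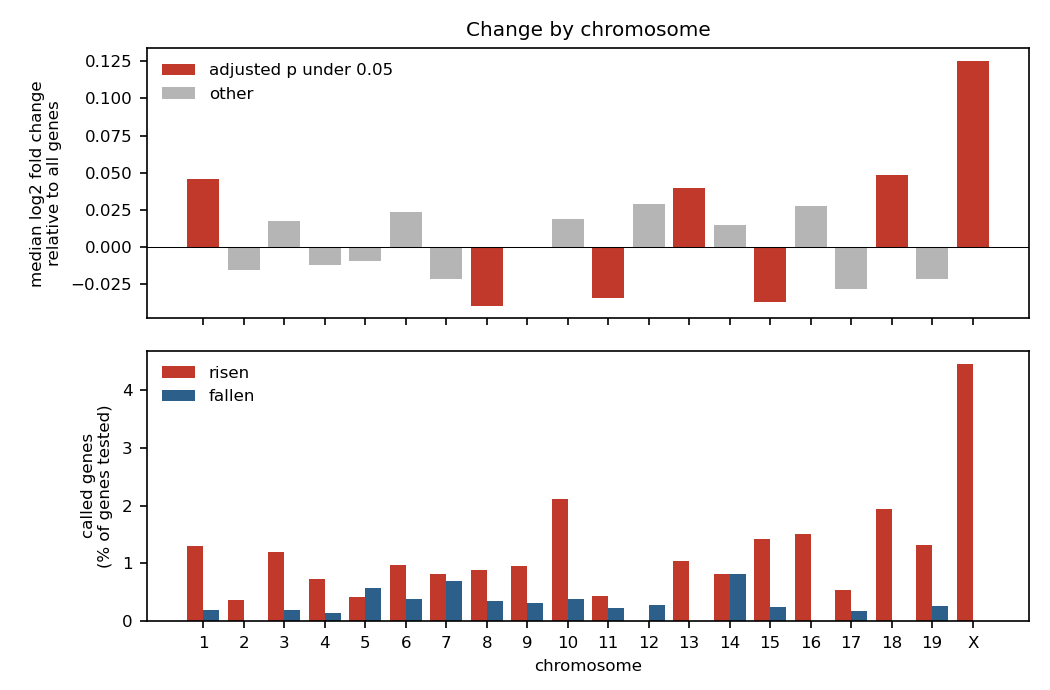
Median log2 fold change of the genes of each chromosome relative to all genes tested (top, red where the adjusted p against random gene sets was under 0.05) and the percent of tested genes called risen or fallen (bottom). The X stands apart with a shift of 0.125 and 17 risen genes of 381, while the shifts of the other chromosomes stay within 0.0482.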

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

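The tests of a whole extra X chromosome, of the normalization, of Lox/Δ3 array 1 and of the list level per array were chosen only after the results they bear on had been seen. With 3 arrays per genotype there are 10 splits of the 6 arrays, too few for a share under 0.05.

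Probes that the annotation used here gives no single gene symbol lie outside the comparisons above, and 36 of the 2941 tested rose in Δ3/Δ3 cells and 5 fell in limma with Benjamini-Hochberg adjustment over all 19652 kept probes. Of the 16711 probes with 1 symbol, 141 rose and 44 fell in that fit. The largest rises were ILMN_1246770 (log2 fold change 1.92 ± 0.26 SE) and ILMN_2668206 (1.86 ± 0.29), and among the falls were ILMN_1231083, detected on no Δ3/Δ3 array and at least 1.85-fold lower, and ILMN_1250392 (-0.81 ± 0.12). Their genes were not named here.

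X-linked genes were higher in Δ3/Δ3 cells by a median of 0.125 relative to all genes, and of the 10 splits of the arrays 1, the real one, reached that shift, the highest other being 0.0971. A gain of a whole X chromosome in all cells is argued against by the 95% bootstrap interval of that median. It ends at 0.175, under the cut-off of 0.3 set here for an extra copy. That interval takes genes as independent, and a gain in part of the cells was not tested and stays open. A bias of weak genes is argued against by the X-linked median lying at percentile 100 of 10000 autosomal sets matched on level. For the excess of risen genes on the X, probes shared within gene families are argued against by a one-sided Fisher exact p of 0.00404 with 1 gene per family. A family counted as risen where any member rose. That test does not bear on the median shift, and probes shared between families were not examined. The low values of Lox/Δ3 array 1 as the whole cause of the shift are argued against by a shift of 0.106 without it. What also stays open is a difference between the few cell cultures or clones that is unrelated to Kdm1a, which the design does not separate from genotype. A higher output of X-linked genes after the loss of LSD1 may therefore be stated only as a hypothesis, found and tested on the same arrays, which several separate clones of each genotype would test.

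More genes rose than fell, 110 against 30. Of the 10 splits 1, the real one, called as many as 140 genes, the highest other being 0. That count does not bear on direction, and every other split mixes the genotypes, which widens the spread within its groups. Risen genes made up at least 73.2% of calls under every other normalization and under the authors' scaled values. This argues against the choice among these normalizations as the cause. All of them bring the arrays to a common level, so an effect shared by all of them was not tested. A floor that lets weak genes rise but not fall is argued against as the whole cause by 20 risen and 7 fallen genes above the median level (two-sided exact binomial p = 0.0192), although at an unadjusted p under 0.05 those stronger genes split evenly, 368 up and 381 down, and all genes 1039 up and 907 down. The low values of Lox/Δ3 array 1, lowest of its genotype in 97 of the 110 risen genes, are argued against as the cause of the imbalance by 84.4% of the 45 genes called without it being risen. No biological explanation is put forward for the imbalance.

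The two-cell list was lower in Δ3/Δ3 cells with camera's preset correlation, but each of the 10 splits, the real one included, gave at least as many lists past the threshold, 1 in the real split and up to 7 in another. That many calls in other splits points to a structure of the arrays in which genes of a list move together, as the estimated correlation of 0.68 in this list shows. A level that differs between cultures of 1 genotype may account for it, since 1 Δ3/Δ3 array, at 8.37, lay within the Lox/Δ3 range of 8.03 to 8.69 (list means; two-sided exact permutation p = 0.2). A single array as the cause is argued against by the list's median staying at or below -0.33 without any 1 array, although the call was lost without Δ3/Δ3 array 1, Δ3/Δ3 array 2 or Lox/Δ3 array 3 (camera adjusted p = 0.0806, 0.118 and 0.101). Tested members such as Tdpoz1, Tdpoz2, Tdpoz3 and Tdpoz4 are relatives whose probes may bind each other's transcripts. That was not examined and could also raise the correlation within the list. No biological explanation is put forward for this list.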

How the results depend on the processing

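The settings with 1 weight per genotype, chromosomes without each array or with a replicate block, the X with an estimated correlation, and lists with an estimated correlation without 1 array were chosen after seeing the data. Against 140 called genes, median scaling gave 261, no filter 24, every probe on its own 226, array weights 512 and an adjusted p under 0.01 gave 2; the others that kept all arrays, the replicate block aside, gave 111 to 199. Median scaling shifted the median of all genes to -0.10. Risen genes were 78.6% of calls, 64.1% with array weights and 66.7% without the filter. The replicate block gave 373 genes, 138 of them among the 140, but the labels do not say that numbers mark a shared batch. Deviations of same-numbered arrays correlated at 0.36, 0.07 and 0.40. Arrays 1 and 3 of each genotype correlated best with their own number. Δ3/Δ3 array 2 did so with Lox/Δ3 array 3 (0.13), and Lox/Δ3 array 2 with Δ3/Δ3 array 1 (0.29). A shared batch was therefore neither shown nor excluded. Leaving out 1 Δ3/Δ3 array gave 0 genes (smallest limma adjusted p 0.0624 to 0.0939), and leaving out 1 Lox/Δ3 array gave 45 to 275. Each of these fits lacked 1 array, so the number of arrays alone does not account for that difference. No called gene changed sign, except Ccl25 on another probe. Among the settings checked for it, Kdm1a lost its call only without a Δ3/Δ3 array or at an adjusted p under 0.01. It ranged from -1.65 to -1.46 without 1 array. Every probe on its own and the mean of probes were not checked for Kdm1a. The number of lists past the threshold (1) became 0 with median scaling, the authors' values, detection p under 0.01 and array weights. It was also 0 with an estimated correlation and with fry's test for a shared direction. It became 2 without the filter, 9 with every probe, and 0 to 4 without 1 array. The two-cell median was -0.61 (adjusted p = 0.0524) with median scaling, -0.45 (0.0513) with the authors' values, -0.49 (0.0573) with detection p under 0.01, -0.22 (0.414) with array weights, -0.49 with an estimated correlation (0.656) or fry (0.416), and -0.71 to -0.33 without 1 array, with adjusted p-values from 1.14e-05 to 0.118. Of 20 chromosomes tested, 7 passed, and 3 to 8 without 1 array; the X shift passed throughout, at 0.106 to 0.148. Turned signs, all uncalled, were Hdac2 (-0.015 median scaling, -0.028 mean of probes), Sox2 (-0.046 median scaling, -0.023 authors' values), Uty (0.029 array weights) and, without 1 array, Nanog (-0.035 to 0.17) and Uty (-0.20 to 0.065). Camera's list direction turned for endoderm (median 0.0053 no filter, 0.17 array weights, -0.30 to 0.29 without 1 array) and neural progenitor (-0.24 array weights, -0.10 to 0.39 without 1 array). It also turned for stress response (-0.052 every probe, 0.0041 array weights, -0.026 to 0.10 without 1 array) and retinoic acid (-0.15 to -0.034 without 1 array). The medians themselves kept their sign for retinoic acid, and for stress response with array weights. Of the other checks on named genes 341 of called genes kept their call and 115 lost it, mostly without a Δ3/Δ3 array, and of uncalled genes 748 stayed uncalled with the same sign and 60 passed; of the checks on lists 382 gave the same result. The causes of these dependences were not tested. Signal over background of 4.24 to 5.46 limits weak genes.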

Other observations

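The gene groups here were chosen only after the values had been seen. So were the tests on them, apart from the random-set test of uncalled members, whose families were still chosen with the values in view. Beyond the genes named above, the risen genes included several with known germ-cell expression. Magea8 and Magea4 of the melanoma antigen family had log2 fold changes of 1.58 ± 0.26 and 1.11 ± 0.15 (SE), the X-linked Xlr5a 1.24 ± 0.21, the oocyte gene Nlrp4c 1.40 ± 0.15, and Pramel14 and Pramel30 1.17 ± 0.21 and 1.16 ± 0.20, with limma Benjamini-Hochberg adjusted p-values from 0.0182 to 0.0433. The oocyte gene Omt2b was detected on no Lox/Δ3 array and rose at least 1.61-fold (limma adjusted p = 0.0227). The X-linked testis genes Usp26 and Tsx rose by 1.55 ± 0.21 and 1.37 ± 0.22 (limma adjusted p = 0.0281 and 0.0369). Many of these belong to families of near-identical copies, so a probe may read more than 1 member, and 11 of the risen genes on the X lay outside the families counted below; relative to all genes, X-linked genes outside those families had a median of 0.112.

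Picked by eye from the 110 risen genes were 7 known from differentiated tissues, with no enrichment tested. Clps, Cela1 and Cela2a, which encode the pancreatic proteins colipase and elastases, had log2 fold changes of 1.57 ± 0.20, 1.02 ± 0.16 and 1.18 ± 0.21 (SE), and the muscle genes Tnni2 and Myl4 1.37 ± 0.22 and 1.07 ± 0.18 (limma adjusted p from 0.0251 to 0.0431). The lens crystallin gene Crygs and the muscle gene Myom2 were detected on no Lox/Δ3 array and rose at least 1.89-fold and 1.81-fold (limma adjusted p = 0.0149 and 0.0281).

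A hypothesis is that loss of LSD1 may raise germ-cell gene families as a class, which separate clones of each genotype would test. Symbols starting with Mage, Xlr, Rhox, Pramel, Nlrp, Tex, Spata, Omt2, Obox or Tdrd gave 63 tested genes, with 11 risen, 0 fallen and a median log2 fold change of 0.43. Membership rested on the symbol alone, and germ-cell expression of each gene was not examined, so other genes may be included. Some of these families were picked because they held risen genes. In the 5 families without a called gene (Rhox, Tex, Spata, Obox and Tdrd, 31 genes, 9 of them X-linked) the median was 0.26, 21 were higher, and camera gave a two-sided p of 0.000446, or 0.0495 with an estimated correlation. The families were chosen with these values in view, so neither p is evidence for the hypothesis. The families differed, with medians of 0.70 for Rhox, 0.22 for Tex, 0.063 for Spata and -0.048 for Tdrd, and 1.91 for the 1 tested Obox gene. The 52 uncalled members of all families had a median of 0.27, which lay at percentile 100 of 10000 random sets of uncalled genes, but some belong to families picked for their called genes and the sets take genes as independent, so whether the shift is that of the called genes alone stays open. Without any 1 array the median of all 63 genes stayed between 0.36 and 0.48. The germline list fixed beforehand was not shifted as a set (camera adjusted p = 0.292), and the difference between it and these families was not tested.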
